A study of Mus musculus with 6 samples.

How the data were processed

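Poly(A)-selected RNA of pancreatic islets from C57BL/6J female mice was sequenced in 6 libraries, 3 of nonpregnant and 3 of pregnant animals. Per the labels' protocols, each library held the pooled islets of 4 mice, each came from its own islet preparation, and the pregnant mice were between days 13 and 15 of gestation. Per the labels, the nonpregnant mice were 12 weeks old, and the pregnant mice of replicates 1, 2 and 3 were 12, 13 and 14 weeks old. The library was the unit of replication, so n = 3 in each group. RNA was fragmented and copied with random primers, and the protocol did not mark the strand.

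The authors deposited 1 table of RPKM values, read counts scaled to transcript length and library total, for 19524 genes, with 1 column per library. Per the file headers, nonpregnant replicates 1 and 2 came from sequencing run 2, and nonpregnant replicate 3 and all 3 pregnant libraries from run 1. The authors also deposited 1 list of reads per library, with the best matches of each read to RefSeq transcripts and the gene, position, strand and number of mismatches of each match. The lists of run 2 hold 36-nt reads with up to 3 mismatches, and those of run 1 hold 32-nt reads with up to 2 mismatches. The genome build was mm9, per the submitters' processing notes. The aligner, the gene counter and the rule by which reads shared between genes were divided are not given in the sources used here. The read lists give positions in transcripts, with no genome coordinates.

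The unit was checked against the read lists. Reads whose best match had at most 2 mismatches were counted per gene, and the deposited RPKM was then used to compute the transcript length it implied. Among genes with no shared reads and at least 20 reads, the length implied in pregnant replicate 3 was compared with that in each other library. It was the same within 1% for 99.98% of 5240 genes in nonpregnant replicate 1 and 100% of 4038 to 5667 genes in the others. The RPKM were thus scaled to the number of reads matched with at most 2 mismatches. That number was 2053947, 1155573 and 2615405 in nonpregnant replicates 1, 2 and 3, and 2648725, 3020627 and 3495323 in pregnant replicates 1, 2 and 3. In a transcript of 1 kb, 1 read equals 0.865 RPKM in the shallowest library and 0.286 RPKM in the deepest. Of the matched reads, between 11.6% and 13.3% per library matched more than 1 gene. Several genes named below had fewer than 50% of their reads in 1 gene alone, which leaves their levels uncertain. They include Gapdh (3.04%), Ube2c (10.2%), Maoa (12.8%), H2-D1 (26.1%), Stat5a (30.6%), H2-K1 (43.2%) and Ins1 (46.0%).

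The main comparison was made with limma 3.58.1 in R 4.3.3, with an intensity trend in the variance prior (limma-trend), on log2(RPKM + 1). All 12545 genes with at least 1 RPKM in at least 3 libraries were tested, all 6 libraries entered the fit, and there were no covariates. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called. Fold changes are on the log2(RPKM + 1) scale, which understates the change of genes at low levels. Where a gene had few reads in 1 group, the ratio of reads found in that gene and in no other, per matched read, is given with an exact 95% interval. Where a group had 0 such reads, the fold was computed against a floor of 3 reads over the group. Intervals and floors cover counting error only. Means are given with the SD.

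The 24 gene lists were fixed before the data were examined, and 23 had the 3 tested members needed for a test. They were tested with camera at an inter-gene correlation of 0.01, adjusted over the 23 lists, and again with a correlation estimated from the residuals and with fry. List members were matched by symbol, with older symbols resolved through the reference tables, in which 16265 table genes found a match by transcript accession, 3005 by symbol or synonym, and 254 none. Asmt, Gins1, Amy2b, Sox10 and Ighm had no match in the table. The rule for the genes named in the text, fixed with the lists, took, from called genes whose groups did not overlap and with a mean of at least 1 RPKM in a group, the 12 with the largest rise and the 12 with the largest fall. It also took every detected member of both serotonin lists and of the prolactin receptor and STAT5 list, 8 islet hormone genes, and the 5 genes with the highest mean. From each other list it took up to 4 called members with the smallest adjusted p or, where none was called, the 2 with the highest mean. Genes outside this rule are named as such, and 1 gene that the rule names is not reported here.

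Because the run is partly shared with the group, the tests of table genes and of lists were also computed with run as a term and within run 1. The estimate is the same in both, namely the mean of the 3 pregnant libraries minus nonpregnant replicate 3, and the fits differ in the spread they use. Run 2 holds nonpregnant libraries only and gives no comparison. For the lists, fry and the estimated correlation were also computed with run as a term. These fits are outside the alternatives that are counted and given as ranges. Other alternatives changed the pseudocount, the filter on low values, the scaling between libraries, the variance trend and the fold tested against, added the replicate number as a block, and left out each library in turn. Reads found in 1 gene were counted and tested with limma-voom, with and without counting repeated reads once. The plan named another count test for these reads over the exons of an annotation. Counts by the gene names in the read lists, tested with limma-voom, took its place, because the read lists give positions in transcripts only. In a further alternative, the first 32 nt of every read were matched exactly to GENCODE M21 transcripts (GRCm38), so that both runs had the same read length and mismatch rule. The same match gave reads of genes that are not in the deposited table, which were tested with limma-voom, with and without run as a term. The planned test over genome bins could not be made from transcript positions. The RPKM values contain no mitochondrial genes, so leaving these out of the totals moves nothing. The run term, run 1 alone, the exact match, and the removal of genes whose reads are mostly shared were chosen after the data were seen.

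The tests were checked on simulated counts with the means and totals of these libraries and the median spread of the pregnant libraries, with 200 changed genes. Limma-trend recovered 72% of 100 genes changed 2-fold and 97% of 100 genes changed 4-fold, with 6 false calls. With a run difference of the measured size added, it recovered 39% and 90%, with 7 false calls. With run as a term on the same data it recovered 44% and 91%, with 9 false calls. At 10 times that variance between libraries, limma-trend without a run term recovered 52% and 98% without and 13% and 82% with the run difference, with 12 and 4 false calls. The nonpregnant libraries were less alike (Spearman 0.861 to 0.935) than the pregnant ones (0.966 to 0.973). Their own spread was not simulated apart from the run difference, so these figures may be too favourable. Single measures of 3 against 3 libraries were compared with exact two-sided permutation tests, whose smallest p is 0.1. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for counting, tables and plots.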

Results

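The transcriptome of mouse pancreatic islets was compared between pregnancy and the nonpregnant state, to find which islet genes differ while the maternal islet adapts to gestation. Islets are the endocrine cell clusters of the pancreas, made up mainly of insulin-producing beta cells. Between 7523843 and 10705832 reads were sequenced per library, and 1155573 to 3495323 of them matched a transcript with at most 2 mismatches. Each pregnant library held more such reads than any nonpregnant library (n = 3 each, exact permutation p = 0.1, the smallest that 3 against 3 can give). Nonpregnant replicate 2 was the shallowest, and 37.7% of its reads contained adapter sequence, against 0.649% to 9.27% in the other libraries.

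Insulin transcripts dominated every library. Ins1 and Ins2 together took 46.2% to 56.6% of all RPKM, with 55.7% ± 1.06 in pregnant and 51.0% ± 4.91 in nonpregnant islets (exact permutation p = 0.3). Transcripts of digestive enzyme genes of acinar cells, which surround the islets, took 4.90% ± 1.71 of RPKM in pregnant and 2.74% ± 1.29 in nonpregnant islets (exact permutation p = 0.2). The first principal component held 52.5% of the variance and placed nonpregnant replicates 1 and 2, sequenced in run 2, apart from the 4 libraries of run 1. Across genes, Spearman correlations of RPKM were 0.966 to 0.973 among the pregnant libraries, 0.945 to 0.948 between them and nonpregnant replicate 3, and 0.861 to 0.899 between runs. Values within run 1, where 3 pregnant libraries stand against 1 nonpregnant library, are therefore given for many lists and genes beside those of all 6 libraries.

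**Figure D1:**
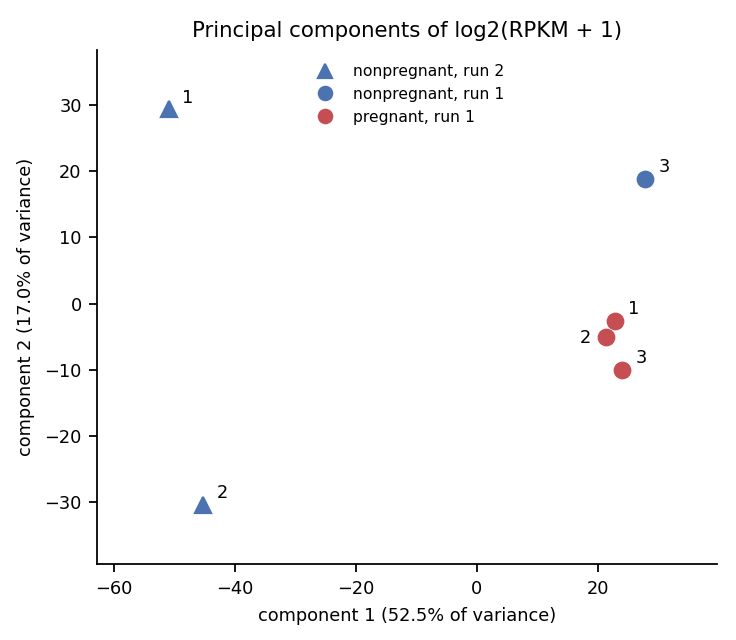
Principal components 1 and 2 of log2(RPKM + 1) over the tested genes, with 1 point per library, numbered by replicate and drawn by group and sequencing run. Component 1, with 52.5% of the variance, separates both libraries of run 2 from the 4 libraries of run 1.

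In pregnant islets 77 genes were higher and 17 lower among the 12545 tested with limma. Among the 12 largest rises were genes with a mean of at most 1.08 RPKM in nonpregnant islets. They included Tph1, the rate-limiting enzyme of serotonin synthesis, Cldn8, a tight junction claudin, Prok1, a secreted prokineticin, and Lrrc55, an accessory subunit of potassium channels. The falls included the activity-dependent transcription factor Npas4, the G protein regulator Rgs2, and heat shock and immediate early genes. In all 94 called genes the groups did not overlap. Over all tested genes 20.6% did not overlap, where chance gives 10%. Of the 94, 56 were also called with run as a term, which called 84 genes (55 higher, 29 lower). Leaving out nonpregnant replicate 2 gave 62 genes, nonpregnant replicate 3 gave 1796, and pregnant replicates 1, 2 and 3 gave 28, 25 and 25. When hormone and acinar genes were left out and the rest rescaled, which raised the median log2 fold change of all genes by 0.23, the split moved from 77 higher and 17 lower to 116 higher and 10 lower.

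Both tryptophan hydroxylase genes, which start serotonin synthesis, rose. Tph1 stood at 0, 2.17 and 0 RPKM in nonpregnant replicates 1, 2 and 3 and at 46.2 ± 3.16 RPKM (SD, n = 3) in pregnant islets (log2 fold change 5.00 ± 0.43 SE, adjusted p = 0.00215, limma). The pregnant libraries held 847 Tph1 reads and the nonpregnant libraries 5, a ratio per matched read of 108 (exact 95% interval 46.0 to 332). Tph2, the isoform best known from serotonin neurons, rose from 0.46 ± 0.193 to 6.27 ± 1.79 RPKM (log2 fold change 2.29 ± 0.27 SE, adjusted p = 0.00956, limma), with 95 reads against 4. Within run 1 the log2 fold changes were 5.56 for Tph1 and 2.52 for Tph2. Of the list for serotonin synthesis, storage and breakdown, 12 members were tested, of which Tph1 and Tph2 rose and none fell. Adjusted over the list alone, 5 were higher and 2 lower. Ddc, which makes serotonin from the product of Tph1, stood at 120 ± 12.6 RPKM in nonpregnant and 177 ± 9.43 in pregnant islets (log2 fold change 0.56, adjusted p = 0.116, limma). The vesicular transporter Slc18a1 had 4.57 ± 1.62 and 7.83 ± 0.505 RPKM, the other vesicular transporter Slc18a2 had a log2 fold change of -0.06, and neither was called. Maoa, Maob, Gch1, Pts, Spr, Qdpr and Aldh2 were detected and not called, with log2 fold changes between -0.66 for Aldh2 and 0.42 for Maob, and within run 1 Maoa went from 0.19 to -0.36 and Qdpr from 0.37 to -0.16. The reuptake transporter Slc6a4 and Aanat, which acts on serotonin in melatonin synthesis, stayed under 1 RPKM in every library. By camera the list was higher (adjusted p = 0.00555), and by fry too (adjusted p = 0.0237). The call was lost with an estimated correlation (adjusted p = 0.264) and by camera with run as a term (adjusted p = 0.0609), but not by fry with run as a term (adjusted p = 0.0384). Its median log2 fold change went from 0.36 to -0.04 with run as a term, and adjusted p over its 22 alternatives ranged from 0.00399 to 0.264. With both run as a term and an estimated correlation, a fit outside these 22, the list was not called.

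Serotonin receptors were near or below the limit of detection. Htr3a, a subunit of the serotonin-gated ion channel, was the only one of the 14 listed receptors with enough signal to be tested, at 4.06 ± 0.506 RPKM in nonpregnant and 2.98 ± 1.28 in pregnant islets (log2 fold change -0.39, adjusted p = 0.543, limma). Htr1b, Htr1d, Htr2b, Htr3b, Htr5a, Htr5b, Htr6 and Htr7 were each below 1 RPKM in every library, and the others were listed at 0. A change in these receptors was not detectable at this depth.

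In the list of the prolactin receptor and STAT5 pathway, Cish, Socs2 and Tnfrsf11b rose, and its kinase and transcription factors were not called. Cish, a suppressor of cytokine signalling that STAT5 induces, went from 25.2 ± 4.93 to 143 ± 3.06 RPKM (SD, n = 3 each), with a log2 fold change of 2.47 ± 0.15 SE (adjusted p = 5.84e-04, limma) and 2.60 within run 1. Socs2, a related suppressor, rose from 10.4 ± 3.96 to 39.6 ± 4.55 RPKM (log2 fold change 1.89, 1.45 within run 1). Tnfrsf11b, the secreted decoy receptor osteoprotegerin, rose from 1.24 ± 0.739 to 12.4 ± 1.79 RPKM (2.62, and 2.12 within run 1). The prolactin receptor gene Prlr had 32.9 ± 13.1 RPKM in nonpregnant and 98.8 ± 6.23 RPKM in pregnant islets, a ratio of the means of 3.00 in which all 3 pregnant libraries lay above all 3 nonpregnant ones. It missed the threshold (log2 fold change 1.65 ± 0.29 SE, adjusted p = 0.0613, limma, and 1.23 within run 1), and 12 of its 21 alternatives called it, over a range of adjusted p from 3.92e-04 to 0.551. Of 17 tested members of the list, 3 rose and none fell. Adjusted over the list alone, 4 were higher and 1 was lower. The list was not called by camera (adjusted p = 0.942, direction up), although its median log2 fold change was -0.18. Jak2, Stat5a, Stat5b, Stat3, Ghr, Socs1, Socs3, Bcl6, Pim1, Pim3, Bcl2l1 and Ccnd2 had log2 fold changes between -0.84 for Bcl6 and 0.17 for Stat3. Igf1, at 0.50 to 2.10 RPKM, was not tested.

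**Figure D2:**
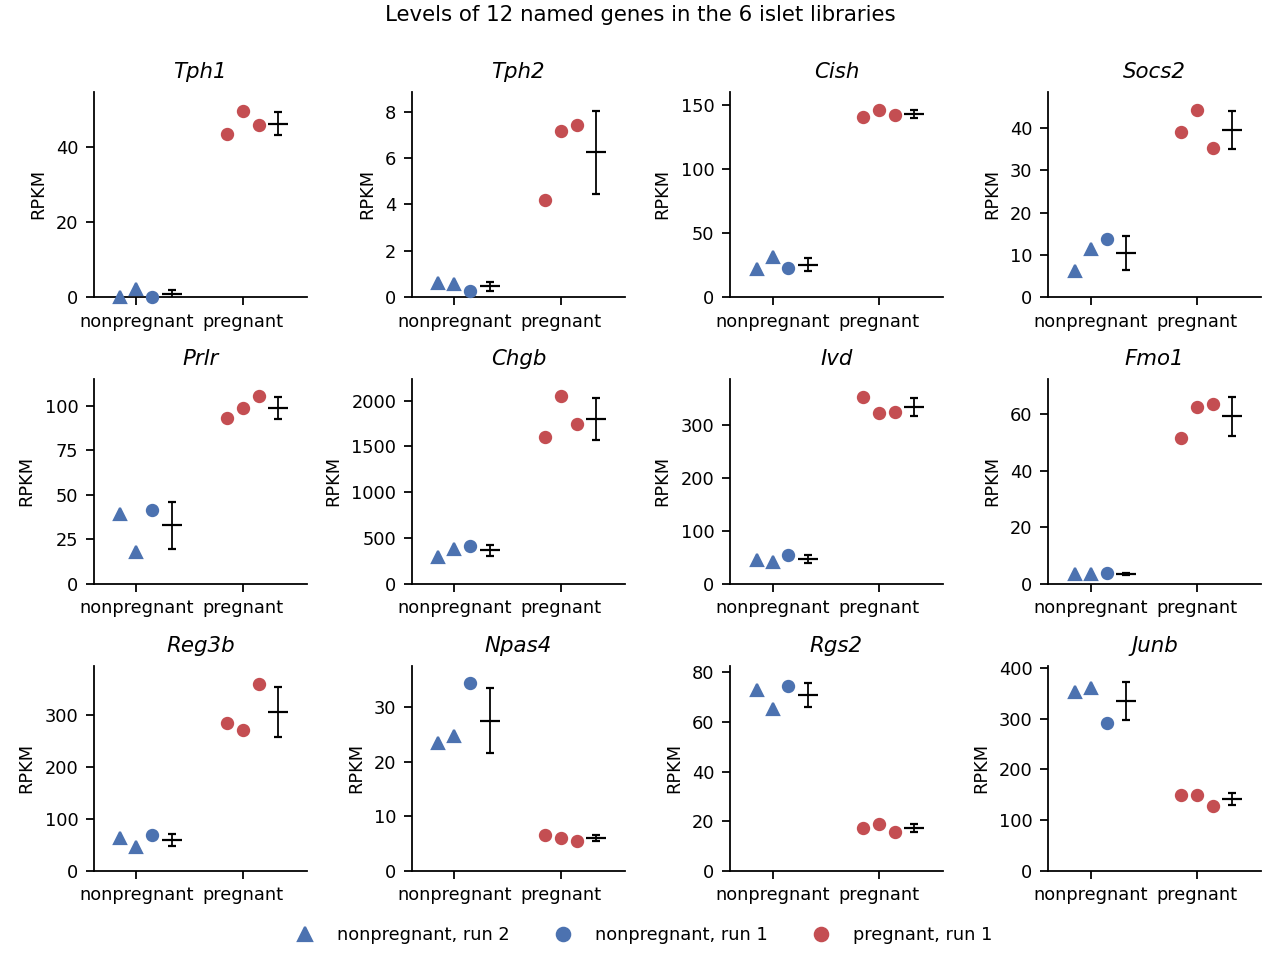
RPKM of 12 named genes, with 1 point per library, coloured by group and shaped by sequencing run, and bars for the mean and SD of 3 libraries. The 3 pregnant libraries lie above all nonpregnant libraries for Tph1 through Reg3b, including Prlr, which missed the threshold, and below them for Npas4, Rgs2 and Junb.

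Among the other 12 largest rises, several genes went from low to moderate or high levels. Ivd, isovaleryl-CoA dehydrogenase of leucine breakdown, rose from 46.9 ± 6.84 to 333 ± 17.2 RPKM (SD, n = 3 each), a log2 fold change of 2.81 ± 0.14 SE (adjusted p = 2.41e-04, limma) and 2.59 within run 1. The flavin monooxygenase Fmo1 rose from 3.54 ± 0.254 to 59.3 ± 6.76 RPKM (log2 fold change 3.73, and 3.63 within run 1). Matn2, a matrix protein of the matrilin family, rose from 8.36 ± 2.35 to 62.9 ± 1.71 RPKM (2.80, and 2.47 within run 1), and Sftpd, the secreted lectin surfactant protein D, from 1.39 ± 0.88 to 18.7 ± 2.93 RPKM (3.12, and 2.82 within run 1). Cldn8 stood at 46.7 ± 3.23 RPKM in pregnant islets, with 998 reads against 11 in nonpregnant islets (ratio 57.7, exact 95% interval 32.1 to 116). Lrrc55 stood at 16.2 ± 0.946 RPKM, with 429 reads against 4 (ratio 68.2, interval 26.4 to 251). Prok1 had 59 reads in the pregnant and 0 in the nonpregnant libraries, and was at least 12.5-fold higher. In 3 of the 12, BC002163, Rps23 and the histone gene Hist1h2bj, more than 99% of the matched reads were shared with other genes, so their levels are uncertain. Reads that matched Rps23 at all did not rise and stood at 391 ± 117 RPM (reads scaled to the library total) in nonpregnant and 234 ± 14.3 RPM in pregnant islets, although its RPKM went from 15.4 ± 9.33 to 360 ± 67.0. Reads that matched BC002163 at all stood at 41.2 ± 15.3 and 38.8 ± 5.35 RPM, against RPKM of 0 and 33.0 ± 14.1.

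Npas4, Rgs2 and several immediate early and heat shock genes fell. Npas4 fell from 27.5 ± 5.99 to 6.00 ± 0.520 RPKM (SD, n = 3 each), a log2 fold change of -2.01 ± 0.19 SE (adjusted p = 0.00351, limma) and -2.34 within run 1. Rgs2 fell from 70.9 ± 4.91 to 17.2 ± 1.73 RPKM (log2 fold change -1.98, and -2.06 within run 1). The cochaperone Dnajb1 fell from 163 ± 16.3 to 58.0 ± 7.28 RPKM (-1.48, and -1.59 within run 1). The inducible Hsp70 genes Hspa1a and Hspa1b had log2 fold changes of -1.36 and -1.62, and over 95% of the reads of each also match another gene, so they are best read together. The transcription factors Nr4a1, Junb and Fosb and the phosphatase Dusp1 had -1.35, -1.23, -1.23 and -1.16. In the list of immediate early and stress genes, 6 of 20 tested members fell and none rose. Adjusted over the list alone 14 were lower and 0 higher. The list median was -0.78, and -1.06 within run 1, where 12 members were called lower and 1 higher with run as a term. The list was lower by camera (adjusted p = 1.42e-12) and by fry (adjusted p = 0.00360). With an estimated correlation it was not called (adjusted p = 0.123), the highest value over its 22 alternatives, of which 21 called it. It was also not called with both run as a term and an estimated correlation, a fit outside these 22. The remaining named falls were Mdm1, from 33.5 ± 6.07 to 15.3 ± 0.159 RPKM, the small nucleolar RNA gene Snord32a, with 11, 10 and 3 reads in nonpregnant replicates 1, 2 and 3 and 0 in pregnant islets, and OTTMUSG00000022083, all of whose reads also match other genes. Of the 34 called genes that the rule named, 14 were called under every alternative in which they were tested. These were Tph1, Cish, Chgb, Reg3b, Ivd, Fmo1, Matn2, Cldn8, Prok1, Lrrc55, BC002163, whose reads all match other genes too, Npas4, Rgs2 and Snord32a. BC002163 and Snord32a were tested in 17 alternatives, all on the RPKM values, and the others in 21. The tests on counted reads and on exact matches did not include these 2 genes. The calls of Socs2, Pycr1, Sdf2l1, Myd116 and Hist1h2bj were lost with run as a term. Over all alternatives, the most often lost were those of Sdf2l1 (11 of 21), Myd116 (10 of 21), Hist1h2bj (10 of 17), Mdm1 (9 of 21) and Fosb (8 of 21).

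Genes of the unfolded protein response and of protein folding in the endoplasmic reticulum were higher as a list. Of 30 tested members, Sdf2l1, part of an endoplasmic reticulum chaperone complex, rose from 95.6 ± 9.42 to 175 ± 18.2 RPKM (SD, n = 3 each, log2 fold change 0.87, and 0.78 within run 1), a call lost in 11 of 21 alternatives. Myd116, the older symbol of Ppp1r15a, whose product reverses the phosphorylation of a translation factor, fell from 105 ± 10.2 to 54.0 ± 5.30 RPKM (-0.94, and -0.79 within run 1), a call lost in 10 of 21. Adjusted over the list alone, 13 were higher and 1 was lower. The median log2 fold change was 0.36, and 0.28 within run 1, with 26 and 24 of 30 members above 0. The list was higher by camera (adjusted p = 3.90e-08) and fry (adjusted p = 0.0117), and not called with an estimated correlation (adjusted p = 0.123), the highest over its 22 alternatives. It was also not called with both run as a term and an estimated correlation, a fit outside these 22. Acinar markers lay in the same direction (list median 0.66, and 0.14 within run 1), and a contribution of acinar cells was not tested.

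In the amino acid and cholesterol synthesis lists 1 gene each was called. Pycr1, which makes proline, rose from 5.90 ± 1.55 to 20.1 ± 1.25 RPKM (SD, n = 3 each, log2 fold change 1.64, and 1.38 within run 1), the only called member of 24 in the amino acid list, in which 3 were higher and 1 was lower adjusted over the list alone. That list was higher by camera (adjusted p = 0.0028, median log2 fold change 0.18) and with run as a term (adjusted p = 0.0226). It was not called by fry (adjusted p = 0.110) or with an estimated correlation (adjusted p = 0.342), in a range of 0.00184 to 0.342 over its 22 alternatives. Dhcr7, the last enzyme of cholesterol synthesis, rose from 9.16 ± 1.75 to 27.6 ± 1.73 RPKM (log2 fold change 1.51, and 1.37 within run 1), while the other 22 tested members of the cholesterol synthesis list were not called (list adjusted p = 0.942, median -0.01). Adjusted over the list alone 1 was higher and 2 were lower. No member was called among 23 of glycolysis and glucose handling (adjusted p = 0.846, median -0.09) or among 25 of the respiratory chain (adjusted p = 0.524, median -0.15), and none adjusted over either list alone. G6pc2, the islet glucose-6-phosphatase, had 569 ± 48.9 RPKM in nonpregnant and 772 ± 56.9 in pregnant islets, and Gapdh 520 ± 59.5 and 474 ± 18.2. Only 3.04% of the Gapdh reads were found in 1 gene, so its level is uncertain. In the respiratory chain, Cox6a1 had 280 ± 49.9 and 211 ± 3.36 RPKM and Atp5b 248 ± 12.4 and 252 ± 5.39.

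Insulin and the other hormone genes were not called. Ins2 stood at 396340 ± 66709 RPKM in nonpregnant and 400102 ± 7785 in pregnant islets (SD, n = 3 each), Ins1 at 73682 ± 18624 and 93382 ± 797, and Iapp at 11637 ± 973 and 11437 ± 407. The trend of the variance prior gives such abundant genes wide errors (SE 1.41 for Ins2 on the log2 scale). Under the alternatives, the lowest adjusted p was 0.299 for Ins2, 0.130 for Ins1 and 0.230 for Iapp, while 1 of 20 alternatives called Gcg lower (adjusted p = 0.0406). Gcg had 18025 ± 1793 and 11337 ± 917 RPKM, with a log2 fold change of -0.67 ± 0.32 SE (adjusted p = 0.399, limma) and -0.76 within run 1. Sst, Ppy, Pyy and Ghrl had log2 fold changes of -0.07, -0.39, -0.35 and -0.62, and of -0.52, -0.67, -0.53 and -0.99 within run 1. Chgb, a chromogranin of the secretory granule, rose from 365 ± 60.2 to 1796 ± 227 RPKM (log2 fold change 2.30, adjusted p = 0.00125, limma, and 2.10 within run 1). With repeated reads counted once its log2 fold change was 0.74 (adjusted p = 0.0377), the smallest over its 21 alternatives. Counting each position once limits the count of a gene with many reads, which can lower this value. Chgb had 1188 to 2938 reads per nonpregnant and 11450 to 16689 per pregnant library. It was the only called gene among 32 beta cell genes, of which 3 were higher and 0 lower adjusted over the list alone. The beta cell list was higher by camera (adjusted p = 3.81e-04, median 0.20), a call lost with an estimated correlation (adjusted p = 0.794) and with run as a term (adjusted p = 0.946), where 15 of 32 members lay above 0, in a range of 2.22e-06 to 0.946 over its 22 alternatives. The list of alpha, delta, PP and epsilon cell genes had no called member among 14, none adjusted over the list alone, and was not called by camera in all 6 libraries (adjusted p = 0.272, median -0.25). With run as a term, 0 of the 14 members lay above 0 (median -0.52) and the list was lower (camera adjusted p = 1.08e-06, fry adjusted p = 0.0384), a call lost with an estimated correlation (adjusted p = 0.296 with run as a term), in a range of 1.08e-06 to 0.886 over its 22 alternatives.

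No gene of the 3 cell cycle lists was called. Among 29 tested mitosis genes the median log2 fold change was 0.13, and 20 lay above 0. Racgap1, which acts in cytokinesis, had 4.51 ± 2.41 RPKM in nonpregnant and 8.47 ± 0.646 in pregnant islets (log2 fold change 0.87, adjusted p = 0.264, limma), and Ube2c, which acts in mitotic exit, 9.21 ± 6.60 and 7.28 ± 1.01 RPKM (-0.09, and 0.95 within run 1). Within run 1, the mitosis median was 0.63 with 28 of 29 members above 0, and the median of 30 DNA replication genes went from -0.01 to 0.53. By camera the mitosis list was higher (adjusted p = 0.0404) and the DNA replication list was not called (adjusted p = 0.942). With run as a term, both were higher (adjusted p = 3.20e-10 and 2.29e-08), but neither was by fry (adjusted p = 0.166 and 0.314) or with an estimated correlation (adjusted p = 0.323 and 0.440). In all 6 libraries neither list was called with an estimated correlation (adjusted p = 0.855 and 0.965) or by fry (adjusted p = 0.693 and 0.980). Adjusted p over 22 alternatives ranged from 1.48e-10 to 0.855 for mitosis and from 7.68e-10 to 0.994 for DNA replication. Without nonpregnant replicate 3 the mitosis list was not called (adjusted p = 0.844) and the DNA replication list was lower (adjusted p = 0.0104), while without nonpregnant replicate 1 the DNA replication list was higher (adjusted p = 0.0174). Adjusted over the list alone, 0 mitosis genes and 1 DNA replication gene were higher. Between nonpregnant libraries, run 2 lay above run 1 by a median of 0.45 for mitosis and 0.91 for DNA replication genes. Leukocyte markers moved the same way, by a median of 2.18, and their median log2 fold change within run 1 was 0.40. Pcna, the sliding clamp of replication, had 58.7 ± 28.7 and 38.7 ± 3.43 RPKM (log2 fold change -0.45, and 0.51 within run 1), and the helicase subunit Mcm7 12.8 ± 5.16 and 12.1 ± 0.559. None of 21 G1 cyclins, CDKs and CDK inhibitors was called, and none adjusted over the list alone (list adjusted p = 0.644, median -0.19), with Ccnd2, cyclin D2, at 131 ± 7.87 and 116 ± 6.79 RPKM and its kinase Cdk4 at 58.7 ± 7.74 and 64.5 ± 4.98.

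Among reported islet growth factors, Reg3b and Reg3a rose. Reg3b and Reg3a, secreted lectins, rose from 59.3 ± 11.6 to 306 ± 48.4 RPKM and from 13.1 ± 5.55 to 59.1 ± 10.1 RPKM (SD, n = 3 each, log2 fold changes 2.35 and 2.17, and 2.12 and 2.87 within run 1). Acinar markers lay in the same direction (list median 0.66, and 0.14 within run 1), and pregnant replicate 3, with the highest acinar share of RPKM (6.81%), was also highest for both genes. Nonpregnant replicate 3, however, had a higher acinar share than pregnant replicate 2 (3.96% against 3.51%). It had less Reg3b (68.8 against 272 RPKM) and less Reg3a (7.12 against 48.1 RPKM). This comparison rests on 1 library of each group, and a contribution of acinar cells was not tested. Reg3b and Reg3a were the 2 called members of 20, and 4 were higher and 0 lower adjusted over the list alone. The list was higher by camera (adjusted p = 0.0404, median 0.07), a call lost with an estimated correlation (adjusted p = 0.794) and with run as a term (adjusted p = 0.829), in a range of 0.0104 to 0.933 over its 22 alternatives.

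Several lists of other cell types had other medians within run 1. The leukocyte list had a median log2 fold change of -1.10 in all 6 libraries and 0.40 within run 1, and was called lower by camera in the former (adjusted p = 0.00555) and higher with run as a term (adjusted p = 2.06e-05). With run as a term the call was lost with an estimated correlation (adjusted p = 0.490) and by fry (adjusted p = 0.586). Cd74, which chaperones class II antigen-presenting molecules, stood at 1562 and 1134 RPKM in nonpregnant replicates 1 and 2, 208 in nonpregnant replicate 3, and 337 ± 48.5 in pregnant islets (SD, n = 3). H2-Ab1, a class II gene, followed the same pattern, at 894, 688 and 131 RPKM and at 151 ± 34.3 RPKM in pregnant islets. The interferon response list was called lower in all 6 libraries (adjusted p = 2.29e-06, median -0.67) and not with run as a term (adjusted p = 0.829, median -0.09), with the class I genes H2-K1 at 561 ± 165 and 347 ± 42.3 RPKM and H2-D1 at 407 ± 117 and 249 ± 23.7. The acinar list was called higher in all 6 libraries (adjusted p = 5.01e-09, median 0.66) and not with run as a term (adjusted p = 0.331, median 0.14), with Ctrb1, a chymotrypsinogen, at 3824 ± 1710 and 7203 ± 1993 RPKM and Ela2a, an elastase, at 3548 ± 1318 and 4979 ± 1257. The red blood cell list was called higher in all 6 libraries (adjusted p = 0.00555, median 0.67) and not with run as a term (adjusted p = 0.594, median -0.12), with the alpha globin genes Hba-a1 and Hba-a2 at log2 fold changes of 0.67 each, and -0.22 each within run 1. Both had 1118 matched reads, none of them found in 1 gene alone, so they are best read as 1 measurement. No member of these 4 lists was called in all 6 libraries, and with run as a term 2 acinar genes were lower, each with over 99% of its reads shared with other genes. The calls of these 4 lists in all 6 libraries were lost with an estimated correlation (adjusted p = 0.794 for each). Over the alternatives, adjusted p ranged from 1.21e-09 to 0.794 for leukocyte, 1.25e-10 to 0.831 for interferon, 1.00e-15 to 0.794 for acinar and 1.15e-05 to 0.794 for red blood cell genes. Adjusted over each list alone, 2 acinar genes were higher and no member of the other 3 was.

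The lists of duct, endothelial, stromal, Schwann cell and neuron, and adipocyte and lymph node markers were not called in all 6 libraries (adjusted p = 0.942, 0.870, 0.0618, 0.846 and 0.230), with medians of 0.08, 0.02, -0.30, -0.03 and -0.88, and held no called gene. Adjusted over each list alone, 2 stromal and 2 adipocyte and lymph node markers were lower, 1 Schwann cell and neuron marker was higher, and no duct or endothelial marker changed. Krt7 and Krt8 of duct cells had log2 fold changes of -0.11 and 0.26 (-0.42 and -0.51 within run 1), and Plvap and Eng of endothelial cells 0.28 and 0.33 (-0.10 and -0.07). Mgp and Sparc of stromal cells had -0.66 and -0.06 (-0.86 and -0.23), Th and Prph of neurons 0.29 and -0.10 (-0.19 and -0.44), and the lymph node chemokines Ccl21a and Ccl19 -1.71 and -1.27 (-0.90 and -0.12). Only 1.37% of the Ccl21a reads were found in 1 gene, so its level is uncertain. With run as a term the duct, endothelial and stromal lists were lower (adjusted p = 0.0171, 0.0171 and 8.43e-05). With run as a term and an estimated correlation none of these 3 was called (adjusted p = 0.296, 0.395 and 0.490), and by fry the duct list was called (adjusted p = 0.0487) and the endothelial and stromal lists were not (0.104 and 0.222), in ranges over 22 alternatives of 0.0167 to 0.999, 0.0135 to 0.981 and 9.03e-06 to 0.799. The Schwann cell and neuron list was not called by camera with run as a term (adjusted p = 0.331) or with an estimated correlation (adjusted p = 0.490), and was lower by fry (adjusted p = 0.0158). Rn4.5s, a small RNA gene and among the 5 genes with the highest mean beside Ins1, Ins2, Iapp and Gcg, had 46294 ± 23575 and 20421 ± 5924 RPKM, with a log2 fold change of -1.05 (adjusted p = 0.457, limma) and 0.01 within run 1.

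Of the 23 lists tested by camera, 11 were called in all 6 libraries, 8 higher and 3 lower. Of these, 4 kept their call and direction with run as a term, namely immediate early and stress genes, the unfolded protein response, the amino acid list and mitosis. By fry 3 lists were called, namely serotonin synthesis, storage and breakdown, the unfolded protein response, and immediate early and stress genes. The amino acid and mitosis lists were not called by fry. With an estimated correlation camera called 0, with 3 at an unadjusted p under 0.05, and adding run as a term to that fit gave no call either.

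**Figure D3:**
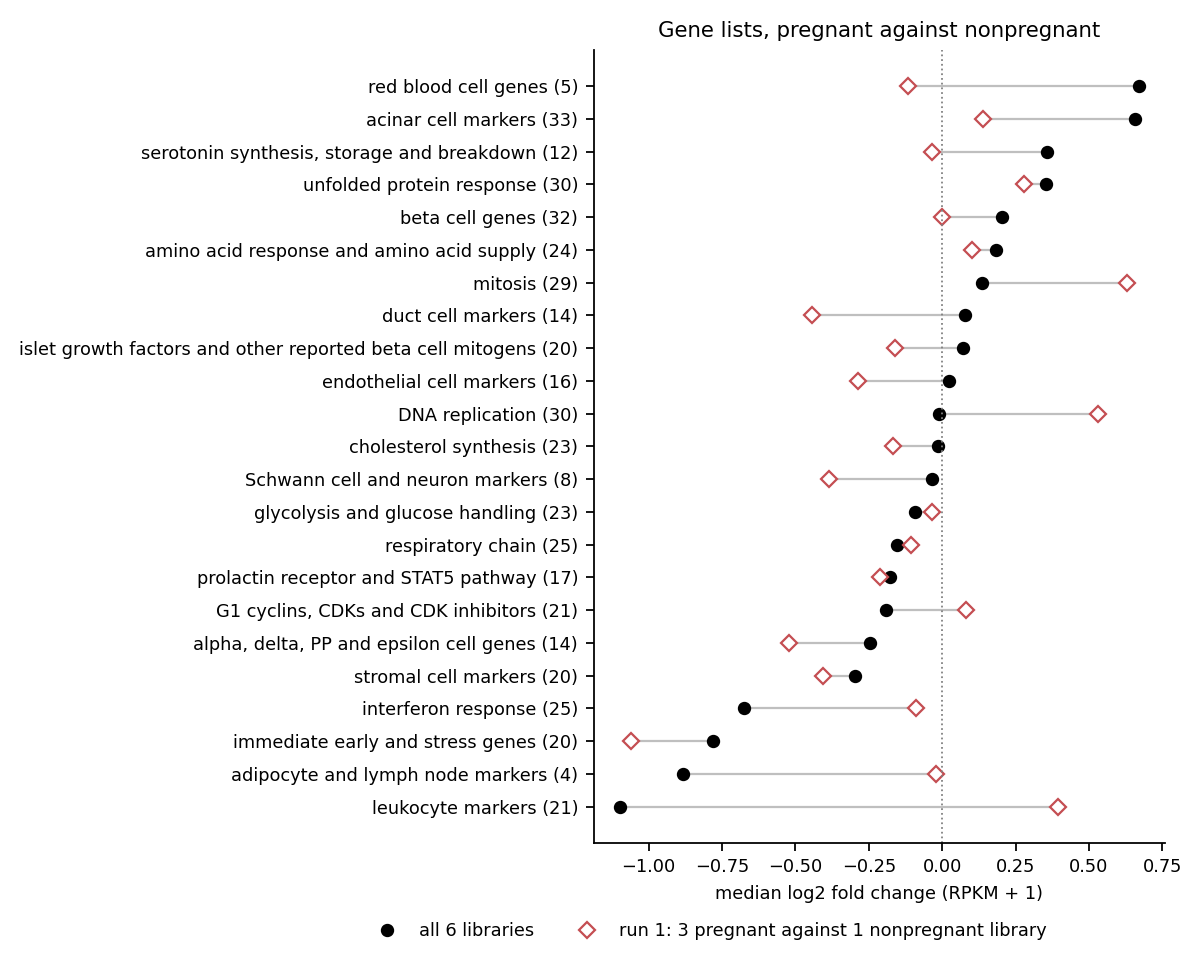
Median log2 fold change of each tested gene list, pregnant against nonpregnant, on the log2(RPKM + 1) scale, in all 6 libraries (filled circles) and within run 1, where 3 pregnant libraries stand against 1 nonpregnant library (open diamonds), with the number of tested members in parentheses. The immediate early and stress list lies below 0 in both, at -0.78 and -1.06, and the leukocyte list changes sign, from -1.10 to 0.40.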

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

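The tests of the sequencing run, of handling, of pregnancy, of the shared Rps23 reads and of other splits of the libraries were chosen after the results were seen.

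Reads of genes that are not in the deposited table also differed between the groups. Of 1098 such genes tested with limma-voom on exact matches, 18 were called (12 higher, 6 lower), and 8 of them also with run as a term (5 higher, 3 lower). The 5 that were higher both ways are given here with their reads in nonpregnant replicates 1, 2 and 3 and pregnant replicates 1, 2 and 3, and positions on GRCm38. Lactbl1, a protein-coding gene on chromosome 4 at 136622621 to 136639110, had 0, 0 and 0 against 96, 95 and 103 reads, at least 70.8-fold higher over a floor of 3 reads over the group (fitted log2 fold change 7.09). Gm27168, on chromosome 8 at 86920477 to 86921147, had 1, 0 and 0 against 25, 40 and 44 reads (5.13). Gm38070, on chromosome 1 at 40238020 to 40244499, had 263, 171 and 308 against 1167, 1747 and 1976 reads (2.23, and 2.35 with run as a term), and lies over Il1r1 on the same strand. Gm17041, on chromosome 9 at 107300380 to 107301838, had 21, 11 and 27 against 107, 151 and 158 reads (2.34). It overlaps Cish on the other strand, and unstranded reads do not separate it from Cish RNA. B830017H08Rik, on chromosome 16 at 17833121 to 17835008, had 66, 53 and 109 against 257, 318 and 346 reads (1.57), and lies 268 bp from Car15. The 3 that were lower both ways were mt-Rnr2, a mitochondrial ribosomal RNA (log2 fold change -1.94, with 396, 173 and 242 against 63, 144 and 91 reads), Gm20481, which overlaps Hspa1a on the other strand (-1.38), and Gm10501, which overlaps Hspa1l on the other strand (-1.53). For the last 2, unstranded reads do not separate them from RNA of the heat shock genes.

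Immediate early and heat shock genes were lower in pregnant islets. The sequencing run stays open, because the values with run as a term rest on 1 nonpregnant library. There the list median was -1.06, and the list was lower by fry (adjusted p = 0.0206) and not called with an estimated correlation (adjusted p = 0.259). Handling of the islets during isolation cannot be told apart from pregnancy, because each preparation belonged to 1 group and no label records the handling. The mean log2 level of the list was 6.04, 6.04 and 6.09 in nonpregnant and 5.39, 5.30 and 5.20 in pregnant replicates 1, 2 and 3 (exact permutation p = 0.1, the smallest possible), and pregnancy stays open, while age was not tested and was higher in pregnant replicates 2 and 3 only, since pregnant replicate 1 was as old as the nonpregnant mice.

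Leukocyte markers were higher in nonpregnant replicates 1 and 2 than in the other 4 libraries. The tables argue against the read length and mismatch rule of the run, since with the first 32 nt matched exactly the median log2 ratio of these libraries to nonpregnant replicate 3 was 2.22. Leukocytes or lymph node tissue in these preparations may account for it, since Ighm, Ighd and Igkc, outside the deposited table, were higher by 2.58, 3.90 and 1.74, while the endothelial and stromal medians were -0.56 and -0.55. Pregnant replicate 1 also had Ighm at 1051 RPM, against 1519 and 1130 in nonpregnant replicates 1 and 2. A lower level in pregnancy stays open, because the median within run 1, 0.40, rests on 1 nonpregnant library.

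Rps23 was higher and its near copy OTTMUSG00000022083 lower in pregnant islets. The division of reads shared among near-identical genes may account for both, since reads that match Rps23 at all had a log2 ratio of -0.74. Sharing between Rps23 and OTTMUSG00000022083 alone does not give these values. Their RPKM were 15.4 and 17.4 in nonpregnant islets and 360 and 0 in pregnant islets, while the matching reads did not rise. With reads matched exactly to transcripts, the log2 fold change of Rps23 was -0.56 and was not called. Neither the reads that match Rps23 at all nor the exact matches showed a rise in Rps23 RNA. A rise in pregnancy is not excluded, because the fall with exact matches was not called. In the read lists, no library had more than 3 reads found in Rps23 and in no other gene.

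Other splits of the 6 libraries into 3 and 3 gave at most 5 called genes against the real 94, so 1 of the 10 splits gave as many. For the gene lists 4 of the 10 splits gave as many as the real 11, and the highest other gave 12. In both cases 10 splits are too few for a share under 0.05. The 3 other splits with 11 or more lists kept nonpregnant replicates 1 and 2, the libraries of run 2, together, and with run as a term 10 lists were called. Setting these 2 libraries against the other 4 called 1585 genes, which points to a structure of the samples. These 2 libraries share their run and also differ from the others in leukocyte markers, so the split does not assign that structure to the run.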

How the results depend on the processing

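The alternatives with run as a term, run 1 alone, the exact match, reads counted with run as a term, and without genes of mostly shared reads were chosen after the data were seen. The causes of the changes below were not tested, except where fewer libraries or a stricter threshold give them by construction. Against 94 genes, leaving out 1 library gave 25 to 1796. Without nonpregnant replicate 3, the groups and the runs coincide. Against 77 higher and 17 lower, reads counted gave 164 genes (133 and 31), repeated reads counted once 147 (113 and 34), a test against a fold of 1.5 25 (21 and 4), run 1 alone 171 (105 and 66), reads counted with run as a term 252 (132 and 120), and adjusted p under 0.1 and 0.01 203 and 46. The replicate block gave 99 genes, 74 of them among the 94, and 12 lists, and deviations from the group means of libraries with the same replicate number correlated at 0.0429, 0.0306 and 0.0252. Of 11 lists, 0 were called by camera with an estimated correlation (3 at an unadjusted p under 0.05) and 3 by fry. Of genes that are not in the deposited table, 18 were called, and 9 with run as a term, of which 8 were among the 18.

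Some directions changed, with adjusted p in the order run as a term, run 1 alone, and reads counted with run as a term. They were higher for DNA replication (2.29e-08, 7.68e-10, 4.35e-07) and leukocyte markers (2.06e-05, 5.23e-05, 2.69e-04), lower for duct (0.0171, 0.0167, 0.0476) and endothelial markers (0.0171, 0.0167, 0.0135), and not called for the interferon response (0.829, 0.831, 0.693). Red blood cell genes turned under run as a term and run 1 alone (0.594, 0.581), beta cell genes under run 1 alone (0.936), and growth factors under reads counted with run as a term (0.773). Leaving out 1 library gave 2.37e-05 to 0.844 for mitosis, whose direction was down without nonpregnant replicate 3, with no call (0.844). For DNA replication it gave 0.0104 to 0.991, lower without nonpregnant replicate 3 (0.0104) and higher without nonpregnant replicate 1 (0.0174). Rps23 had a log2 fold change of -0.56 with exact matches, and Cd74 0.76 for reads counted with run as a term.

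Under the alternatives chosen beforehand, 1410 results for named genes kept direction and side of the threshold, 49 turned direction with no call either way, 89 lost the call and 35 gained it. For lists these were 336, 25, 37 and 11, and 2 more turned direction with a call on 1 side only. Only the 34 called among the 95 tested named genes, and the 11 called among the 23 tested lists, could lose a call. Not run were the 1 kb bins and the repeated reads for signal outside the table, which need genome positions, and the totals without mitochondrial reads, which the RPKM do not hold. In the shallowest library, 1 read in a 1 kb transcript equals 0.865 RPKM, which limits calls at low levels.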

Other observations

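The genes in this part lie outside the naming rule and were chosen after their values were seen. Several called enzymes rose. Ehhadh, of peroxisomal fatty acid oxidation, went from 4.52 ± 0.716 to 27.5 ± 0.927 RPKM (SD, n = 3 each, log2 fold change 2.37, adjusted p = 7.91e-04, limma), and Ogdhl, related to a citric acid cycle enzyme, from 58.2 ± 10.4 to 209 ± 17.2 RPKM (1.84). The carbonic anhydrase Car15 went from 22.5 ± 3.41 to 94.3 ± 1.62 RPKM (2.03). Within run 1 the log2 fold changes were 2.19, 1.57 and 1.94. The peptide genes Vip and Grp rose from 26.9 ± 3.96 to 86.2 ± 14.9 RPKM and from 3.13 ± 1.81 to 13.5 ± 2.78 RPKM, with log2 fold changes of 1.61 and 2.34 within run 1. Gpr119, a lipid receptor, went from 4.79 ± 1.20 to 12.5 ± 0.191 RPKM (1.24, and 0.91 within run 1), a call lost with run as a term (adjusted p = 0.194). Gpr26, an orphan receptor, had 80 reads in pregnant and 0 in nonpregnant islets, at least 16.9-fold higher.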
